A study of Mus musculus with 9 samples.

How the data were processed

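Stat5a, Stat5b and IgG chromatin immunoprecipitates of mouse CD4+ T cells were sequenced at 8 h, 13 h and 2 rounds of Th2 differentiation, 9 libraries in all. Per the labels the series holds 22 lanes of data, the growth and treatment protocols being given only by reference to a publication that was not used here. Each library has 1 deposited list of mapped reads, in which the values are the start and end of each read in bp of the mm8 build, 1 line per read and not normalized, with a mismatch class and a strand. Each of the 6 ChIP libraries also has 1 deposited list of peaks by the authors, in which the values are the start and end of each peak in bp, with no height, score or p-value. The aligner, the peak caller, its threshold and the use of the IgG libraries in calling are not given in the sources used here. Reads were 25 bp long, and 4 libraries also held 24 bp reads: 38.0% of Stat5a and 49.7% of IgG at 13 h, and 54.5% of Stat5a and 77.3% of IgG after 2 rounds. In Stat5a at 13 h, 14.3% of the 25 bp starts recurred among 24 bp starts 1 bp downstream. In the other 3 libraries between 0.507% and 0.680% did, against between 0.299% and 0.543% at other offsets. The 24 bp starts were therefore moved by 1 bp in all 4 libraries, though the offset is clear only in Stat5a at 13 h.

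Depth ranged from 3130228 to 9036070 reads per library, and each library was scaled to RPM, reads per 1000000 of its own total. A read was counted in a region when its 5' end fell in it. Shares of reads carry Wilson intervals, and ratios of 2 libraries carry exact conditional (Clopper-Pearson) intervals, all at 95%. No p-value is given for a comparison of libraries, since each group has 1 library. Where a library had 0 reads in a region, its fold is a bound with that library set at a floor of 3 counts, which is not the lower limit of an interval. Peaks within a list were joined where they overlapped, and the 6 lists were joined into 43771 merged regions covering 24.0 Mb. A merged region was called higher or lower when the interval of the ratio lay wholly above 2 or below 0.5. This rule, the comparisons and the rule for named regions were fixed before the data were examined.

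Named regions are the 10 with the most RPM above IgG at each stage (mean of Stat5a and Stat5b). They also include, per comparison and direction, up to 10 called regions with the largest ratio among those with a higher count of at least 30, of which the text gives examples. Ties at 0 reads were ordered by the reads of the other library. Overlaps needed 1 bp, and their expectation came from 1000 circular shifts of a list within chromosomes (100 for alternatives). Regions were also called here in the same way for all libraries, in windows of 200 bp with a Poisson tail probability under 1e-06 against the higher of the genome-wide rate and the IgG rate of the stage. For this the libraries were thinned to 3130228 reads, or to 2050801 distinct starts, the numbers of Stat5a at 8 h, which was therefore kept whole. A region was treated as heaped when, in any library, 1 start and strand held over 50% of at least 20 reads, which 56 regions met. Groups of regions were formed from nuclear regions in at least 2 lists, without heaped regions, with gaps under 10 kb. These groups, the heaped regions and the 1151 regions found in all 6 lists without heaps were defined after the data were seen.

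Alternatives were scaling by reads outside regions or by the median ratio over regions with reads in both libraries, each start and strand counted once, the upper 50% of each list by reads, 50% reciprocal overlap, regions in at least 2 lists, pooled IgG, reads moved 75 bp downstream, and calling at equal depth. Added after the data were seen were 25 bp reads alone, regions without heaps, regions from the lists of the other antibody, and calling on distinct starts. The calling rule was tested on simulated data with 100 regions raised and 100 lowered by 6-fold at the depths of a library pair. Levels came from the 8 h library. Changed regions were drawn only from those with an expected 13 h count of at least 30 before the change. The median deposited peak at 8 h and 13 h held between 8 and 21 reads, so recovery in most regions was not tested. The rule found 100 raised and 79 lowered regions for Stat5b from 8 h to 13 h. For Stat5a it found 100 raised and 71 lowered regions, and the false calls were 15 and 6. The simulated counts were Poisson draws without repeated starts, so these false calls can be too few for real libraries. Between the IgG libraries of 8 h and 13 h the same rule called 113 regions higher and 202 lower. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

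Genes bound by Stat5, the location of peaks relative to genes and the STAT motif in peaks had been planned and were left out, because the gene table at hand (GRCm38.p6) and the peaks (mm8) are in different builds and no genome sequence was used here. The gene table served only to count the 21631 protein-coding genes per chromosome. Peaks were not re-aligned or re-called from raw reads.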

Results

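Binding of Stat5a and Stat5b, a pair of related transcription factors that act downstream of IL-2 and other cytokines, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse CD4+ T cells. The cells were taken at 8 h, at 13 h and after 2 rounds of Th2 differentiation, the path by which CD4+ T cells become IL-4 producing helper cells. An IgG control was sequenced at each of the 3 stages, which gives 9 libraries, 1 per antibody and stage. There are no replicates, so each comparison compares those libraries, not the conditions. At 8 h the mapped reads numbered 3130228 for Stat5a, 6867047 for Stat5b and 6241015 for IgG. At 13 h they numbered 8311042, 9036070 and 7525521, and after 2 rounds 6645271, 7656900 and 5787254, in the same order. Levels are given as RPM, reads per 1000000 mapped reads of the library. Distinct combinations of start and strand made up between 61.0% (Stat5a after 2 rounds) and 74.1% (Stat5b at 8 h) of a library. Regions are named by their position in the mm8 mouse build, since no gene positions in that build were used here. All intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

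The first question is how many places each factor occupied at each stage. Stat5b had its fewest deposited peaks at 8 h, 3990, more at 13 h, 13268, and the most after 2 rounds, 33692. Stat5a peaks numbered 5585 at 8 h, 14302 at 13 h and 9791 after 2 rounds, so the Stat5a list was longest at 13 h. When regions were called in the same way from equally many reads, Stat5b again went up, through 2522, 7052 and 18678 regions. Stat5a then gave 21462, 5533 and 12748 regions, so its 8 h library had the most of all 6 and its 13 h library the fewest of its 3. The Stat5a 8 h library set the common depth, so it was not thinned and kept all its repeated starts. Each IgG library called against another IgG library in this way gave between 1628 and 2491 regions, close to the 2522 of Stat5b at 8 h. Calls from equally many distinct starts, added after the data were seen, gave 636, 2813 and 12003 regions for Stat5b, 2525, 1414 and 3211 for Stat5a, and between 65 and 112 for IgG. Of the regions from equally many reads, between 16.3% (Stat5a at 8 h) and 85.7% (Stat5b after 2 rounds) lay in the deposited peaks. On distinct starts the share was between 77.8% (Stat5b at 8 h) and 95.6% (Stat5b after 2 rounds), with 92.2% for Stat5a at 8 h. How the 6 libraries rank in number of regions thus depends on the calling. Peaks also differed in width, with a median of 95 bp for Stat5b at 8 h and 562 bp for Stat5b after 2 rounds. The other 4 lists had median widths between 243 and 364 bp.

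**Figure D1:**
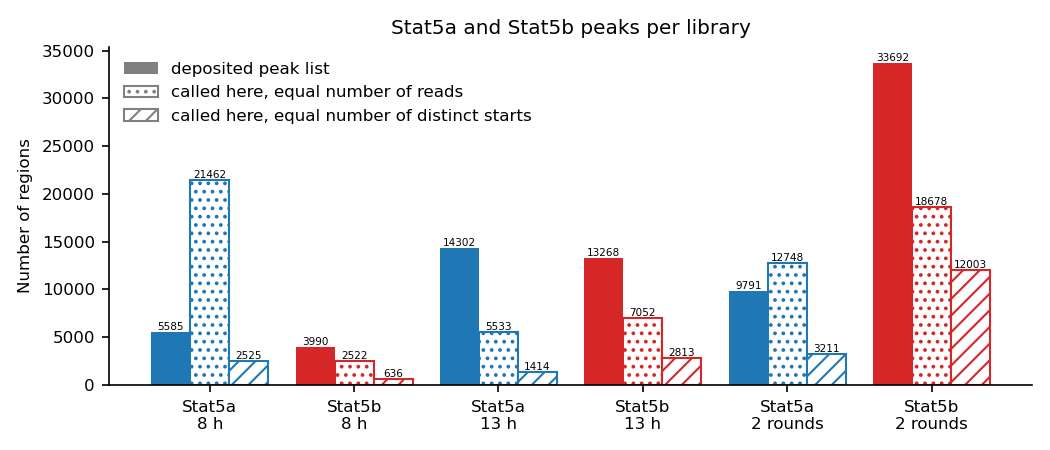
Number of regions (vertical axis) for Stat5a (blue) and Stat5b (red) at each stage, as deposited (filled bars) and as called here from equally many reads (dotted bars) or distinct starts (hatched bars), 1 library per bar and therefore no error bar. Stat5b is highest after 2 rounds in each count, at 33692, 18678 and 12003, while Stat5a is highest at 13 h as deposited (14302), at 8 h from equally many reads (21462) and after 2 rounds from distinct starts (3211).

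Peaks of every list held a larger share of ChIP reads than of reads of the IgG library of the same stage. Each list comes from the ChIP library counted in it, so an excess over IgG is favoured by that choice and is no test of binding. Stat5b after 2 rounds stood apart in its share, with 18.7% of its reads in its peaks against 2.30% of IgG reads. These peaks covered 20.6 Mb, at 9.10 RPM per kb against 1.12 in IgG. Stat5a after 2 rounds had 4.67% of its reads in 3.63 Mb of peaks, at 12.9 RPM per kb against 2.33 in IgG. At 13 h, Stat5b peaks covered 5.23 Mb and held 4.69% of its reads (8.98 per kb against 1.60). Stat5a peaks of that stage covered 3.92 Mb and held 3.35% (8.56 against 1.75). At 8 h, Stat5a had 3.53% of its reads (95% Wilson interval 3.50 to 3.55) in 1.83 Mb (19.2 per kb against 4.15). Stat5b at 8 h had 3.21% of its reads in 0.447 Mb (71.9 per kb against 42.0), only 1.71 times the IgG share (1.70 to 1.72). With each start and strand counted once, its share was 0.778% against 0.221% in IgG, a ratio of 3.53 (3.45 to 3.61). Without the heaped regions the 95% interval of its share was 0.992% to 1.01% against 0.491% in IgG, at 22.4 RPM per kb against 11.0, a ratio of 2.03. Counting each start once raised the ratio of Stat5a at 8 h from 4.63 to 8.13. It raised that of Stat5a after 2 rounds from 5.52 to 8.48, and lowered that of Stat5b after 2 rounds from 8.13 to 7.80. In 25 bp reads alone, the ratios after 2 rounds lay close together, at 6.56 (6.49 to 6.63) for Stat5b and 6.37 (6.24 to 6.51) for Stat5a.

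The share of single peaks above IgG, which the choice of peaks in the same ChIP library also favours, depended on the list and on the setting. The interval of the ratio of ChIP to IgG lay wholly above 1 in 95.8% of Stat5a peaks at 8 h, 86.3% at 13 h and 92.9% after 2 rounds. For Stat5b the shares were 63.2%, 92.0% and 95.2%. The Stat5b share at 8 h was 33.1% with each start and strand counted once, 33.8% with reads moved 75 bp downstream and 85.6% with IgG pooled over the stages. That of Stat5a at 13 h fell to 46.5% with each start and strand counted once. No IgG read fell in 1873 of 3747 joined Stat5b peaks at 8 h and in 4897 of 31744 after 2 rounds, the extremes of the 6 lists.

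The strongest nuclear regions recurred only in part across stages. Ranking used the mean of Stat5a and Stat5b, so recurrence across antibodies was not tested. The chromosome 9 and chromosome 16 regions given here were among the 10 strongest at every stage. That of chromosome 1 was among them at 8 h and 13 h, and that of chromosome 17 at 13 h and after 2 rounds. That of chromosome 10 was among them only after 2 rounds. The region on chromosome 9 from 107153387 to 107156833 held the most reads above IgG of all nuclear regions after 2 rounds, and at 8 h and 13 h only the heaped region of chromosome 7 described at the end held more. Stat5a there stood at 94.6, 87.8 and 139 RPM at 8 h, 13 h and 2 rounds, and Stat5b at 41.1, 119 and 322. IgG stood at 6.09, 8.37 and 3.63. The ratio to IgG was 15.5 (11.1 to 22.4) for Stat5a and 6.74 (4.80 to 9.73) for Stat5b at 8 h. After 2 rounds it was 38.4 (24.9 to 62.3) and 88.8 (58.0 to 144). Next came the region on chromosome 16 from 23902784 to 23905036, with Stat5a at 72.5, 52.7 and 79.2 RPM and Stat5b at 30.6, 84.2 and 205, against 4.01, 1.86 and 2.25 for IgG. On chromosome 1, from 60990082 to 60991533, Stat5a had its highest level at 8 h, with 73.8, 33.3 and 67.0 RPM, while Stat5b stood at 23.4, 53.3 and 81.0. On chromosome 10, from 94844625 to 94848058, Stat5b stood at 7.72, 29.5 and 164 RPM and Stat5a at 22.0, 24.2 and 48.5. On chromosome 17, from 34812280 to 34813817, Stat5b stood at 18.1, 53.9 and 156 RPM and Stat5a at 38.7, 34.8 and 29.5.

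**Figure D2:**
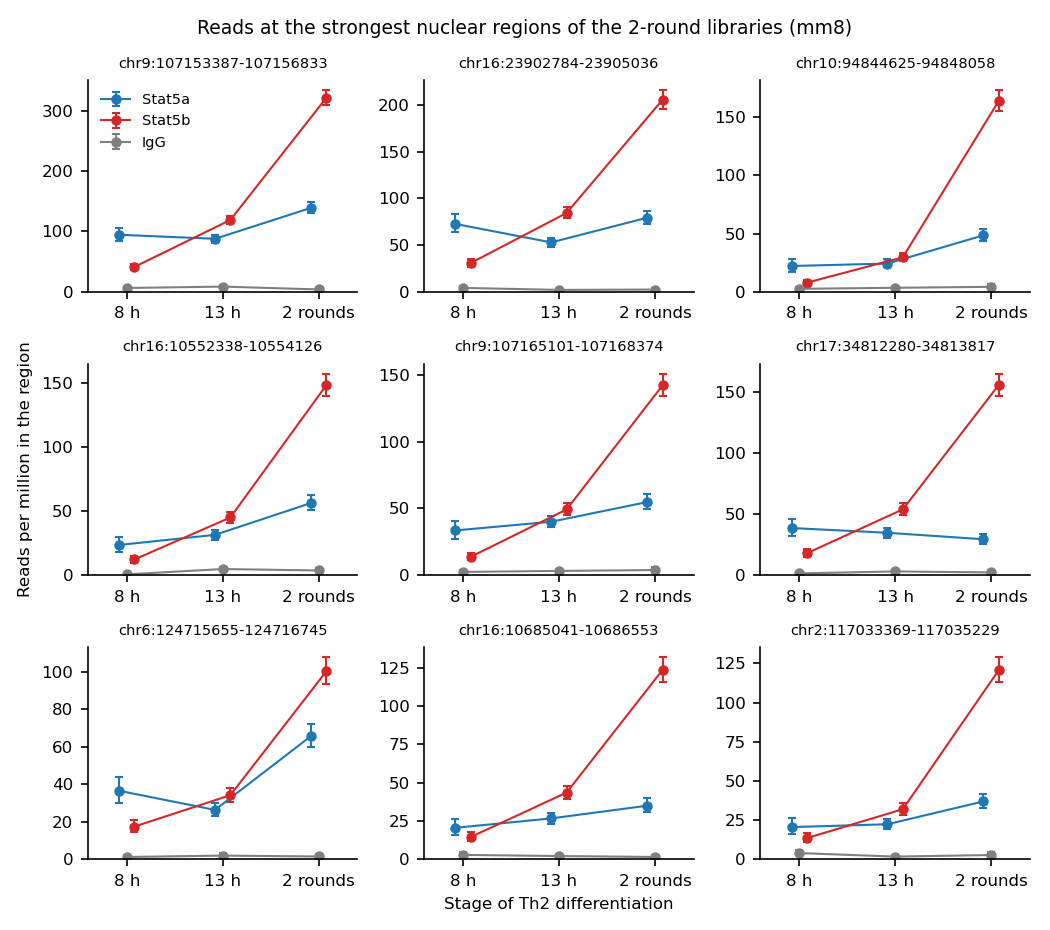
RPM (vertical axis, a separate scale per panel) at the 9 nuclear regions with the most reads above IgG after 2 rounds, by stage, for Stat5a (blue), Stat5b (red) and IgG (grey), with 95% Poisson intervals of 1 library each. Stat5b is below Stat5a at 8 h and above it after 2 rounds in every panel, for example 41.1 against 94.6 and then 322 against 139 RPM at the chromosome 9 region from 107153387 to 107156833, but scaling by the median ratio (a log2 shift of 1.28 after 2 rounds) leaves the later interval above 1 in 4 panels, across 1 in 4 and below 1 at chromosome 6, with 0.953 (0.883 to 1.03) at that chromosome 9 region.

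The lists of the strongest regions also held places where IgG was high. These were the mitochondrial region from 10943 to 15727, with 345, 324 and 139 RPM for Stat5a, Stat5b and IgG at 8 h, and the region on chromosome 2 from 98466999 to 98468251, where IgG at 8 h stood at 1076 RPM beside 1221 for Stat5a. Neighbouring regions of the lists, on chromosome 2 from 98462994 to 98463910 and on chromosome 14 from 39187412 to 39187916, were likewise high in IgG, at 661 and 208 RPM. IgG at 8 h also stood at 51.8 RPM against 108 for Stat5a in the mitochondrial region from 2625 to 4795, and at 53.4 against 87.5 on chromosome 11 from 3091075 to 3094543.

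The 16023 nuclear regions found in at least 2 lists and free of heaped reads were grouped where they were less than 10 kb apart. This gave 11296 groups, 208 of them with 5 or more regions and 8458 with a single region. The heaped region of chromosome 7 and the mitochondrial regions are thus not ranked here. Groups were ranked by summed reads, which favours groups of many regions, and clustering was not tested. Among these groups, 1 of 7 regions on chromosome 9 from 107152367 to 107172446 held the most reads above IgG at each stage, with 119, 187 and 418 RPM as the mean of Stat5a and Stat5b. The group of 14 regions on chromosome 2 from 11533859 to 11581322 ranked 2 at each stage, with 114, 149 and 242 RPM above IgG. Of the 10 strongest groups of each stage, 6 were shared by all 3 stages.

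**Figure D3:**
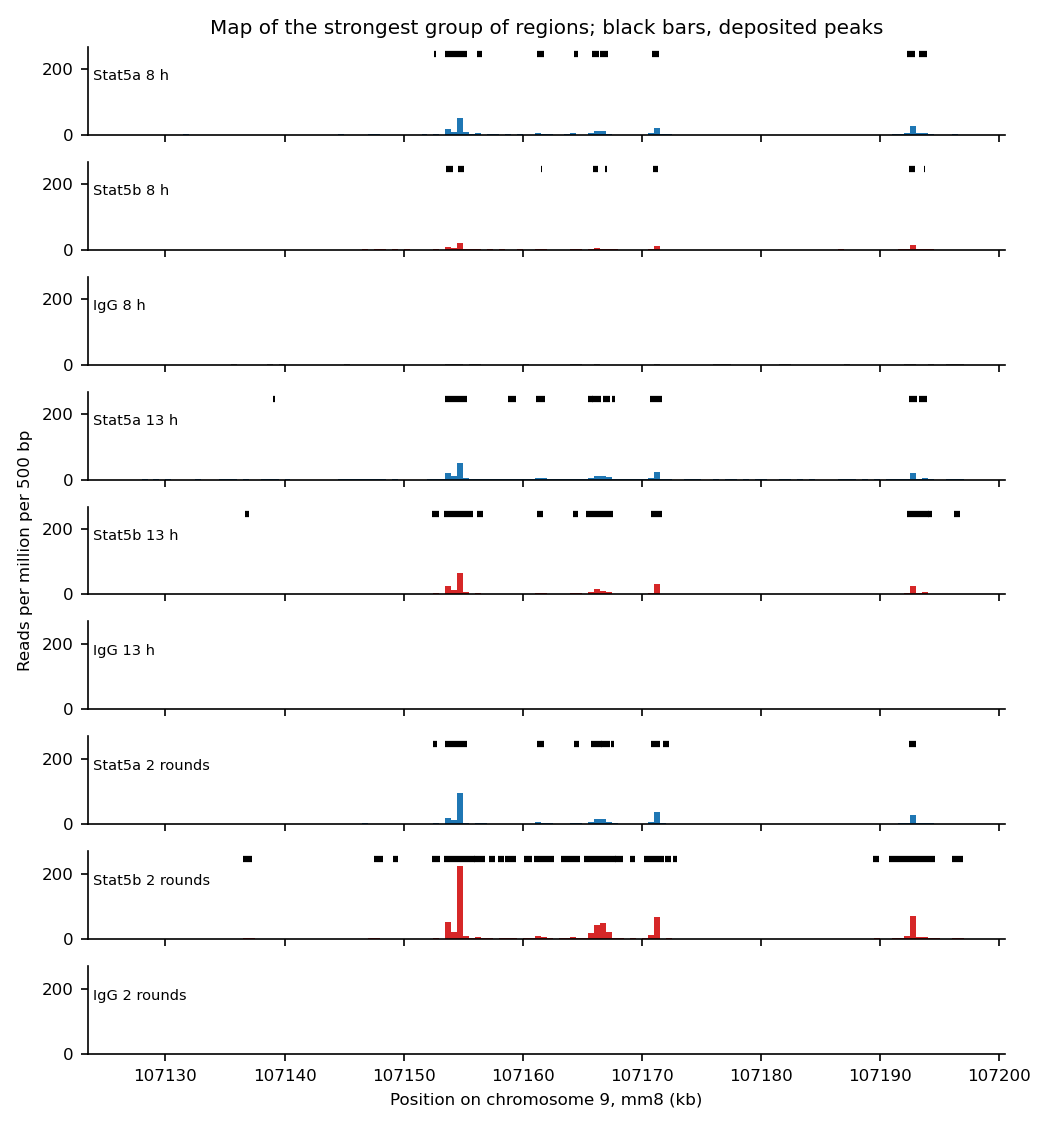
RPM per 500 bp along chromosome 9 (horizontal axis, kb, mm8) around the strongest group of regions, 1 row per library with a common vertical scale, and deposited peaks as black bars. Stat5b after 2 rounds has the tallest bars, in the region that holds 322 RPM, and IgG stays near 0.

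Most regions were found in few lists. The 6 lists joined into 43771 merged regions with a median width of 488 bp. Of these, 27727 were in a single list and 1152 were in all 6. A peak at all 3 stages, for either antibody, was found in 3761 regions (8.59%), and 20994 regions (48.0%) had a peak after 2 rounds only. Regions with peaks at 13 h and 2 rounds but not at 8 h numbered 7324, those at 13 h only 8770 and those at 8 h only 1553. Regions at 13 h only had low median levels at that stage, 1.08 RPM for Stat5a and 0.221 for Stat5b. Regions with a peak after 2 rounds only had a median of 0.775 RPM for Stat5b at 13 h against 0.399 in IgG, so a missing peak does not show a missing signal.

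The next comparison asks whether Stat5a and Stat5b occupied the same places at a stage. After 2 rounds, 8221 of 9558 Stat5a peaks (86.0%) overlapped a Stat5b peak, and 24.8% of the peaks of the longer Stat5b list overlapped a Stat5a peak. At 13 h, 39.5% of Stat5a peaks overlapped Stat5b peaks and 42.4% of Stat5b peaks overlapped Stat5a peaks. At 8 h the shares were 31.6% and 56.4%. Circular shifts of 1 list within chromosomes gave a mean of 1.30% after 2 rounds, 0.363% at 13 h and 0.0965% at 8 h for the share of Stat5a peaks. Over the 1000 shifts of each pair, the 95% range ended at 1.60% at most. With an overlap of at least 50% of both peaks required, the shares of Stat5a peaks at the 3 stages in order were 6.57%, 30.3% and 46.3%. With regions called from equally many distinct starts they were 15.6%, 54.5% and 73.5%, and from equally many reads 2.76%, 1328 of 5533 regions, and 31.8%. Read levels of Stat5a and Stat5b across the 16044 regions in at least 2 lists had a Spearman correlation of 0.532 at 8 h, 0.596 at 13 h and 0.509 after 2 rounds. Over all 43771 regions it was 0.432, 0.223 and 0.536. The correlation of Stat5b with IgG over these was 0.260, 0.295 and 0.307, and that of Stat5a with IgG 0.216, 0.0585 and 0.221, so at 13 h the antibodies agreed no more than Stat5b and IgG did. Over the regions in at least 2 lists, the correlations with IgG were between 0.0336 and 0.266. These correlations are across regions, which are not independent replicates.

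How often peaks of an early stage were found again later depended on the overlap rule. With an overlap of 1 bp, of the Stat5b peaks at 8 h, 68.8% overlapped a Stat5b peak at 13 h and 71.9% one after 2 rounds, and 76.7% of those at 13 h overlapped one after 2 rounds. For Stat5a the same shares were 53.0%, 46.0% and 24.8%, lower in each pair. Shifted lists gave means between 0.256% and 1.35%. The later lists differ in covered length, and the difference between the antibodies was not tested. With at least 50% of both peaks required, the order of the antibodies turned for the 8 h lists, with 45.5% of Stat5a and 2.64% of Stat5b peaks found at 13 h, and 35.5% and 0.641% after 2 rounds, the Stat5b 8 h peaks being narrower. From 13 h to 2 rounds it did not turn, with 2818 of 14084 Stat5a and 5360 of 12771 Stat5b peaks.

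Relative to all reads, the change of binding from 8 h to 13 h went different ways for the 2 antibodies. Among the 1151 regions found in all 6 lists and free of heaped reads, the median Stat5b level went from 4.37 to 9.85 RPM, a median ratio of 2.22, and 216 of them rose and 0 fell. The median Stat5a level in the same regions went from 9.58 to 6.50 RPM, a median ratio of 0.711, and 0 rose and 26 fell. IgG stood at 0.961 and 1.06 RPM. These regions were chosen after the data were seen, as peaks in every ChIP library compared. Such a choice can favour high counts in the library with the fewest reads, Stat5a at 8 h. Its effect on the Stat5a fall in these regions was not tested. A region counts as having risen or fallen when the 95% interval of its ratio lies wholly above 2 or below 0.5. On distinct starts, 50 rose and 0 fell for Stat5b, and 0 rose and 5 fell for Stat5a. Of the 9 nuclear regions plotted above, 7 rose for Stat5b and 2 did not pass, and 3 passed on distinct starts. The ratio was 2.90 times (2.54 to 3.32) on chromosome 9 from 107153387 to 107156833, and 3.83 times (2.84 to 5.24) on chromosome 10 from 94844625 to 94848058.

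Over all 43771 merged regions, 2308 rose and 133 fell for Stat5b from 8 h to 13 h, and 127 rose and 940 fell for Stat5a. IgG, compared in the same way, gave 113 and 202. With each start and strand counted once, the numbers were 495 and 3 for Stat5b, 3 and 242 for Stat5a, and 7 and 30 for IgG. Over regions with reads in either library the median log2 ratio was 1.06 for Stat5b and 0.40 for Stat5a, so the sign for Stat5a depends on the regions used. Over regions with reads in both libraries it was 0.93 for Stat5b and -0.20 for Stat5a. Scaling by that median in place of all reads gave 153 higher and 730 lower for Stat5b, a split of 17.3% higher in place of 94.6%, so the Stat5b rise is relative to all reads. For Stat5a it gave 287 and 715, or 28.6% higher in place of 11.9%. In the 1151 shared regions it gave 6 higher and 0 lower for Stat5b, and 0 and 7 for Stat5a. Reads of 25 bp alone gave 202 and 473 for Stat5a, with a median log2 ratio of 0.018 over regions with reads in both libraries. Stat5a also differed between the 24 bp and 25 bp reads of its own 13 h library, where 59 regions passed as higher and 452 as lower in the 24 bp reads. On distinct starts these were 0 and 30. In the IgG library of 13 h the split went the other way, with 234 higher and 72 lower, or 19 and 2 on distinct starts.

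Among the regions with the largest changes from 8 h to 13 h, Stat5a fell on chromosome 16 from 52048496 to 52049141, to 0.0897 times its level (0.0401 to 0.182), with 42 reads at 8 h and 10 at 13 h. Distinct starts gave 0.164 (0.0699 to 0.355). It fell to 0.106 times (0.0445 to 0.227) on chromosome 6 from 129194693 to 129195213. Both calls held with each start counted once, as did those of 5 of the 10 regions with the largest fall and 3 of the 10 with the largest rise. The region on chromosome 9 from 123700160 to 123700933 was among these 3, with 0 Stat5a reads at 8 h and 42 at 13 h, which is at least 5.27-fold higher with the 8 h library set at the floor of 3 counts. Stat5b rose on chromosome 15 from 5430370 to 5430964, with 0 and 34 reads, at least 8.61-fold higher. It also rose on chromosome 7 from 75618243 to 75619320, with 1 and 51 reads, a ratio of 38.8 (6.65 to 1560), or 21.5 (3.51 to 885) on distinct starts. Of the 10 named Stat5b rises, 9 held on distinct starts. Only 6 regions qualified as named Stat5b falls, 5 of them with reads heaped at a single start, and 0 held on distinct starts.

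From 13 h to 2 rounds, the shared regions that changed relative to all reads nearly all rose, for both factors. In the 1151 regions of all 6 lists, the median Stat5b level went from 9.85 to 17.8 RPM, a median ratio of 1.93, and 305 rose and 3 fell. Stat5a went from 6.50 to 9.03, a median ratio of 1.37, and 73 rose and 0 fell. On distinct starts, 173 rose and 1 fell for Stat5b, and 27 rose and 0 fell for Stat5a. IgG stood at 1.06 and 1.21. On chromosome 10, the region from 94844625 to 94848058 rose 5.56 times for Stat5b (4.86 to 6.36), or 3.37 times (2.84 to 4.01) on distinct starts, and stood at 2.00 times for Stat5a (1.67 to 2.40). On chromosome 17, from 34812280 to 34813817, Stat5b rose 2.89 times (2.60 to 3.21) while the Stat5a ratio was 0.848 (0.704 to 1.02). On distinct starts this Stat5b ratio was 1.99 (1.69 to 2.34), which ends the call.

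Over all merged regions, 10995 rose and 279 fell for Stat5b between these stages, and 3402 rose and 1835 fell for Stat5a. IgG gave 282 and 41. Distinct starts gave 6483 and 29 for Stat5b, 1142 and 26 for Stat5a, and 27 and 2 for IgG. Over regions with reads in both libraries the median log2 ratios were 1.37 for Stat5b and 0.32 for Stat5a. Scaled by that median, Stat5b had 1662 higher and 2413 lower (40.8% higher in place of 97.5%) and Stat5a 2145 and 2747 (43.8% in place of 65.0%), so the direction of both splits turns with this scaling. In the 1151 shared regions Stat5b then had 6 higher and 108 lower, which also turns, and Stat5a 33 and 6. The Stat5a falls were fewer in 25 bp reads, 274, and in regions found in at least 2 lists, 175. Within the Stat5a library of 2 rounds, 898 regions passed as higher and 1234 as lower in the 24 bp reads against the 25 bp reads, or 111 and 177 on distinct starts. In the IgG library of 2 rounds 14 and 721 passed.

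Some 2-round regions had no reads at 13 h. Stat5b on chromosome 19, from 58411080 to 58411712, had 0 reads at 13 h and 110 after 2 rounds, at least 43.3-fold higher. A region on chromosome 2, from 152041124 to 152041840, had 0 and 90, at least 35.4-fold higher. For Stat5a, the region on chromosome 10 from 44621265 to 44621980 had 0 and 48 reads, and that on chromosome 3 from 95383258 to 95383851 had 0 and 39, at least 16.3-fold higher. All 10 named rises of each antibody held on distinct starts. Falls were smaller in number: Stat5a on chromosome 4, from 134380704 to 134381321, had 37 reads at 13 h and 0 after 2 rounds, at least 9.86-fold lower. Stat5b on chromosome 4, from 142416312 to 142416736, had 35 and 0, at least 9.89-fold lower.

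**Figure D4:**
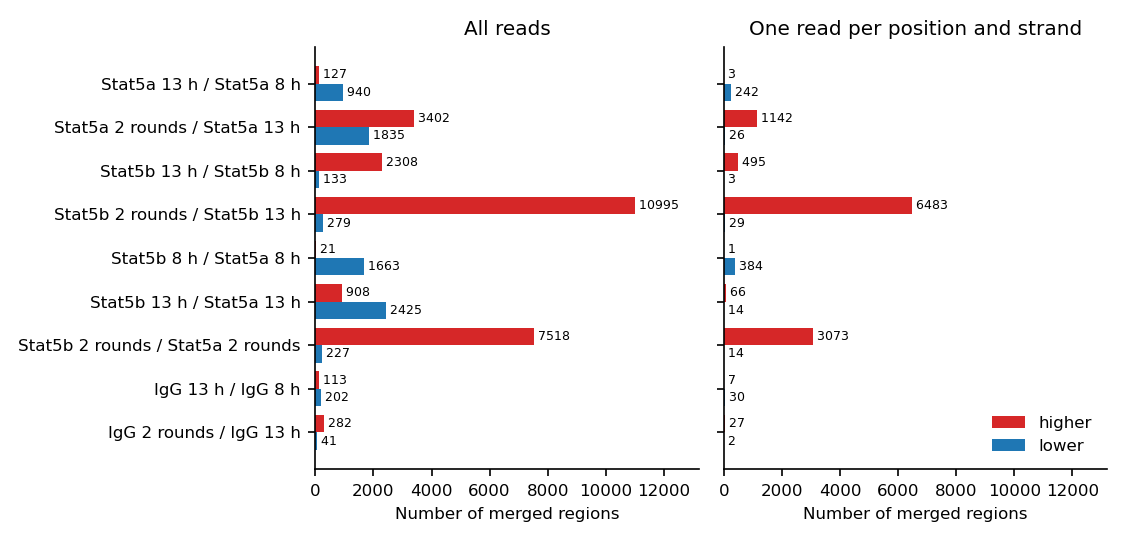
Number of merged regions (horizontal axis) higher (red) or lower (blue) in the library named first on each line, with a 95% interval of the ratio wholly above 2 or below 0.5, counting all reads (left) or each start and strand once (right). Stat5b from 13 h to 2 rounds has the most, 10995 higher with all reads and 6483 with distinct starts, and IgG at most 282 and 30; scaled by the median ratio in place of all reads, the same Stat5b comparison has 1662 higher and 2413 lower.

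The last comparison sets Stat5b against Stat5a at the same stage, and relative to all reads its direction turned between stages. In the 1151 shared regions the median ratio of Stat5b to Stat5a was 0.456 at 8 h, 1.46 at 13 h and 1.93 after 2 rounds. At 8 h, 0 of these regions were higher and 108 lower in Stat5b, at 13 h 13 and 0, and after 2 rounds 269 and 0. On distinct starts these were 0 and 18, 3 and 0, and 142 and 0. On chromosome 9 from 107153387 to 107156833 the ratio was 0.434 (0.368 to 0.513), then 1.36 (1.23 to 1.49), then 2.31 (2.15 to 2.50). The chromosome 17 region from 34812280 to 34813817 had the largest ratio after 2 rounds of the 9 nuclear regions plotted, 5.27 (4.53 to 6.17), after 0.467 (0.361 to 0.605) at 8 h. On distinct starts these 2-round ratios were 1.72 (1.53 to 1.94) and 3.04 (2.46 to 3.78).

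Over all merged regions, Stat5b was higher in 21 and lower in 1663 at 8 h, in 908 and 2425 at 13 h, and in 7518 and 227 after 2 rounds. On distinct starts the numbers were 1 and 384, 66 and 14, and 3073 and 14, so the majority at 13 h turned. At 13 h the regions in at least 2 lists had 325 higher and 73 lower, and reads of 25 bp alone had 355 and 1398. Over regions with reads in both libraries the median log2 ratio of Stat5b to Stat5a was -0.87 at 8 h, 0.31 at 13 h and 1.28 after 2 rounds. Scaled by that median, Stat5b was higher in 283 and lower in 264 regions at 8 h (51.7% higher in place of 1.25%), in 442 and 3307 at 13 h (11.8% in place of 27.2%), and in 292 and 1543 after 2 rounds (15.9% in place of 97.1%). In the 1151 shared regions it then had 0 higher and 3 lower, 2 and 0, and 2 and 34, so the direction after 2 rounds turns. A comparison of antibodies also carries the difference in how well each precipitates its factor, so a ratio of 1 has no fixed meaning.

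Single regions set the antibodies further apart. At 8 h, Stat5b on chromosome 7, from 45549084 to 45549706, stood at 0.0781 times Stat5a (0.0269 to 0.188; 0.121 on distinct starts), and on chromosome 18, from 62294189 to 62295044, at 0.0798 times (0.0302 to 0.180). At 13 h, Stat5b on chromosome 12, from 103029093 to 103029735, had 50 reads against 1 for Stat5a, a ratio of 46.0 (7.88 to 1852), or 20.3 (3.27 to 836) on distinct starts. After 2 rounds, the region on chromosome 4 from 43046368 to 43047181 had 53 Stat5b reads and 0 Stat5a reads, at least 15.3-fold higher, and the region on chromosome 11 from 100666349 to 100667020 had 50 and 0, at least 14.5-fold higher. All 10 named regions higher in Stat5b after 2 rounds held on distinct starts. Of the 10 named as lower, 7 had reads heaped at a single start and 1 held on distinct starts.

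The region on chromosome 7 from 125339709 to 125340091 held more reads above IgG than any other at 8 h and 13 h, but nearly all its reads began at 2 positions. Stat5a had 6287, 4142 and 569 reads there at 8 h, 13 h and 2 rounds, Stat5b 566, 1198 and 426, and IgG 265, 424 and 87. In RPM these were 2008, 498 and 85.6 for Stat5a, 82.4, 133 and 55.6 for Stat5b, and 42.5, 56.3 and 15.0 for IgG. The positions 125339883 on the plus strand and 125339968 on the minus strand span 86 bp. They took between 95.1% (IgG at 8 h) and 100% (IgG after 2 rounds) of the reads, within 2 bp. Counted once per start and strand, the 6287 Stat5a reads at 8 h came to 14. In the 2 kb on either side, the 6 ChIP libraries pooled had 91 distinct starts and the 3 IgG libraries 45, a ratio of 1.01 after scaling by distinct starts (0.701 to 1.48). In the nearest 200 bp they had 8 and 6, a ratio of 0.667 (0.203 to 2.33), so binding at this place was neither shown nor excluded.

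**Figure D5:**
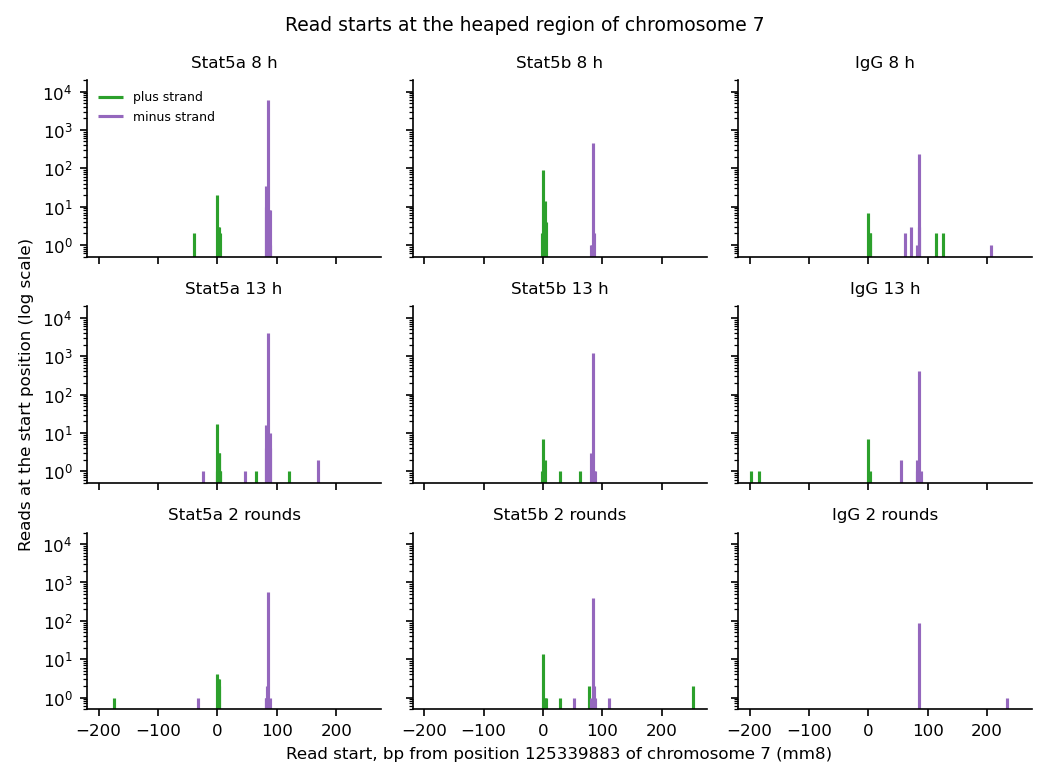
Reads per start position (vertical axis, log scale) against distance in bp from position 125339883 of chromosome 7 (horizontal axis), plus strand in green and minus strand in purple, 1 panel per library. All 9 libraries, IgG included, have their tallest line on the minus strand at the same place, with 6204 reads within 2 bp of it for Stat5a at 8 h and 87 for IgG after 2 rounds.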

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

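The tests of fixed ends, of reads that are not mouse DNA, of an extra copy, of the lists of the other antibody, of 25 bp reads alone and, as a test of copied fragments, of distinct starts were chosen after the data were seen.

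Relative to all reads, the antibodies differed in the direction of change from 8 h to 13 h, with 127 regions higher and 940 lower for Stat5a, and 2308 higher and 133 lower for Stat5b. Scaled by the median ratio, 287 were higher and 715 lower for Stat5a and 153 and 730 for Stat5b, a balance that centring on the median partly sets, while in the 1151 shared regions it gave 0 and 7 for Stat5a and 6 and 0 for Stat5b, and the difference was not tested, since each is 1 library per stage. For the Stat5a decline, meaning more regions lower than higher, the values argue against regions picked for high 8 h counts as the whole cause. In regions of the Stat5b lists lower regions were still 5.94 times (4.70 to 7.59) as many as higher ones, against 1.71 (1.34 to 2.19) in IgG. Intervals of such ratios of region numbers treat the regions as independent counts. All regions of a ratio come from the same pair of libraries, so these intervals cover neither differences between libraries nor counting error of reads. The values also argue against copied fragments as the whole cause of the excess of lower regions. On distinct starts 242 regions were lower and 3 higher, a ratio of 80.7 (27.3 to 394), against 4.29 (1.84 to 11.6) in IgG. Of the 940 lower regions, however, only 237 were lower in both counts, so most single falls did not hold without repeated starts. The 24 bp reads at 13 h are argued against as the whole cause. In 25 bp reads alone the ratio was 2.34 (1.98 to 2.77), against 0.523 (0.407 to 0.669) in IgG. It was 7.40 in all reads (1.79 in IgG), so the 24 bp reads may account for part of the decline. Depth also differed: Stat5a had 3130228 reads of 25 bp at 8 h and 5154110 at 13 h, IgG 6241015 and 3787690. With all reads, 13 h had 8311042 for Stat5a and 7525521 for IgG. IgG is thus no reference at like depth. The low depth of the Stat5a 8 h library may also account for part. So may a lower yield of the 13 h Stat5a immunoprecipitation or lower Stat5a binding at 13 h. None of these was tested, and there was no replicate.

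Reads at the chromosome 7 region were found in IgG as well, 265 at 8 h, 424 at 13 h and 87 after 2 rounds, data outside the antibody comparisons. The median share of reads within 2 bp of the 2 end positions was 98.8% over the 9 libraries, but these positions were taken from the heap itself and nearly all reads lay at the minus end, so a PCR product of fixed ends stays open. Binding at this place stays open as well. In the 2 kb on either side the ratio of distinct starts to IgG was 1.01 (0.701 to 1.48), and an interval that reaches 1.48 does not exclude weak binding, so the bound set beforehand was too loose. The nearest 200 bp held only 8 and 6 distinct starts, a ratio of 0.667 (0.203 to 2.33).

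At position 60832754 of chromosome 16, 78604 IgG reads at 8 h and 62191 after 2 rounds began on the minus strand, beside 140061 of Stat5b at 8 h and 3 of IgG at 13 h. Position 107783674 of chromosome 3 had 6622 IgG reads at 8 h and 5379 after 2 rounds, beside 10284 of Stat5b at 8 h. Of all reads at these positions, 98.7% carried 2 mismatches, which is consistent with reads that are not mouse DNA placed with mismatches. An extra copy of the locus in these cells that reaches beyond 50 bp is argued against, since the density of distinct starts in the 2 kb on either side was 0.685 times the mean of the same libraries (0.455 to 0.990), and 0.714 times that of the other 6 libraries (0.447 to 1.11). Other libraries of the same stages had few such reads. At the chromosome 16 position Stat5a at 8 h had 14, and Stat5a and Stat5b after 2 rounds had 22 and 33. At the chromosome 3 position these libraries had 0, 3 and 0. A copy carried by all cells of a stage would raise each of its libraries, so these values argue against it. The design gives no biological explanation to test, and the origin of the reads stays open.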

How the results depend on the processing

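The settings of 25 bp reads alone, the lists of the other antibody, regions without heaps and calling on distinct starts were chosen after the results were seen. In the simulation, which changed only regions with an expected 13 h count of at least 30, 79 and 71 of 100 falls were found. These were fewer than rises, and whether depth sets this was not tested. No replicate could be left out, and no paired analysis was possible because each group has 1 library. Results on genes, peak location and the motif were not run. A count or a share of peaks moved when it changed beyond 1.5 times. A share of reads was held against IgG, and an overlap against the shifts. Pooled IgG (6 results), scaling by reads outside regions (20), 50% reciprocal overlap (9) and regions without heaps (26) left every result within 1.5 times, or on the same side of IgG or of the shifts. Within these limits, the share of reads of Stat5b at 8 h went from 3.21% to an interval of 0.992% to 1.01% without heaps and that of Stat5a at 8 h from 3.53% to 3.32%. Pooled IgG took the Stat5b peaks at 8 h above IgG from 63.2% to 85.6%. An overlap counted as unmoved whenever it lay above the shifts, a limit that large falls can still meet. With 50% reciprocal overlap, Stat5b 8 h peaks found at 13 h went from 68.8% to 2.64%. Those found after 2 rounds went from 71.9% to 0.641%, with the range of the shifts ending at 0.0801%. Except where a construction is named, the cause of each move was not tested.

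With each start and strand counted once, the share of peaks above IgG was 33.1% for Stat5b at 8 h and 46.5% for Stat5a at 13 h. Regions higher and lower were 3 and 242 (Stat5a, 8 h to 13 h), 1142 and 26 (Stat5a, 13 h to 2 rounds), 495 and 3 (Stat5b, 8 h to 13 h), 6483 and 29 (Stat5b, 13 h to 2 rounds). For Stat5b over Stat5a they were 1 and 384 at 8 h, 66 and 14 at 13 h, 3073 and 14 after 2 rounds. With 25 bp reads alone, they were 202 and 473 (Stat5a, 8 h to 13 h), 2170 and 274 (Stat5a, 13 h to 2 rounds), 355 and 1398 (Stat5b over Stat5a, 13 h), 4848 and 359 (the same, 2 rounds). With reads moved 75 bp downstream, 33.8% of Stat5b peaks at 8 h stood above IgG.

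Scaled by the median ratio, 287 were higher for Stat5a from 8 h to 13 h and 2145 from 13 h to 2 rounds. Stat5b had 153 and 730, then 1662 and 2413. Stat5b over Stat5a had 283 and 264 at 8 h, 442 higher at 13 h, 292 and 1543 after 2 rounds. By construction this scaling sets the median ratio of regions with reads in both libraries to 1.

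In regions of at least 2 lists, which are fewer, higher and lower were 78 and 316, then 2161 and 175 for Stat5a, and 3 lower, then 4559 and 68 for Stat5b. Stat5b over Stat5a had 9 and 881, 325 and 73, 3153 and 13. In regions of the lists of the other antibody, they were 83 and 493, then 216 lower for Stat5a, and 1209 and 14, then 4085 and 79 for Stat5b.

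Called at equal depth, regions numbered 21462 (Stat5a, 8 h), 2522 (Stat5b, 8 h), 5533 (Stat5a, 13 h), 7052 (Stat5b, 13 h) and 18678 (Stat5b, 2 rounds). On distinct starts they numbered 2525, 636, 1414, 2813, 3211 and 12003 for Stat5a and Stat5b at 8 h, 13 h and 2 rounds. The upper 50% of each list by reads had, by construction, 2792, 1995, 7151, 6634, 4895 and 16846 peaks in the same order.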

Other observations

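The tests in this part were chosen after the data were seen.

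A group of 6 regions on chromosome 1 from 132704482 to 132732644 went from a low to a high rank between the stages. It ranked 1408 among all groups at 8 h, 173 at 13 h and 10 after 2 rounds, with 4.29, 19.7 and 126 RPM above IgG. Stat5b held 35, 236 and 1437 reads there and Stat5a 43, 194 and 526, against 32, 38 and 45 for IgG. The Stat5b ratio of 2 rounds to 8 h was 36.8 (26.4 to 53.1) and the Stat5a ratio 5.76 (4.22 to 8.06). The group was chosen after its values were seen. A group of 9 regions on chromosome 6 from 129174277 to 129203892 went the other way in rank, from 5 at 8 h to 9 and 24, with 69.1, 61.7 and 90.2 RPM above IgG. Its Stat5a ratio of 13 h to 8 h was 0.493 (0.429 to 0.568).

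Other groups kept a high rank at every stage. On chromosome 1, 9 regions from 108412837 to 108448595 held 83.1, 85.3 and 182 RPM above IgG, with ranks 3, 3 and 4. On chromosome 16, 15 regions from 10660970 to 10702654 held 45.4, 73.0 and 185, with ranks 12, 7 and 3. The 10 strongest groups together held 3.01%, 2.61% and 2.37% of the summed reads above IgG of the groups at 8 h, 13 h and 2 rounds. Heaped and mitochondrial regions are in none of the groups.

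Chromosome 11 had the most merged regions per Mb, 27.8, and the X chromosome the fewest, 5.26. Across the 20 chromosomes, peaks per Mb were set against protein-coding genes per Mb from the GRCm38.p6 table, 7 relations in all. For Stat5b after 2 rounds, Pearson r was 0.720 (permutation p 8e-05, adjusted 0.00056) and Spearman rho 0.812 (permutation p 1e-05, the smallest the permutations can give, adjusted 7e-05). Without chromosomes 7 and 11, the farthest in gene density, r was 0.713. For all merged regions r was 0.699 (permutation p 0.00028, adjusted 0.00098) and rho 0.774 (permutation p 0.00012, adjusted 0.00042), with r 0.681 without these chromosomes. For Stat5a after 2 rounds r was 0.415 (permutation p 0.0713, adjusted 0.0713) and rho 0.319 (permutation p 0.172, adjusted 0.172), with r 0.380 without them, so that relation did not pass. The other 4 lists had r between 0.457 and 0.648, with adjusted p between 0.00406 and 0.0517. Chromosomes are not independent samples of the cells, and a chromosome dense in genes differs in other ways too.

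At position 85971754 of chromosome 15, 2267 of 2332 Stat5a reads at 13 h were 24 bp long. For IgG at 13 h these were 1516 of 1526 reads. After 2 rounds they were 2070 of 2076 for Stat5a and 1302 of 1319 for IgG. Stat5b at 13 h, which held no 24 bp reads, had 60 reads there. The heap thus went with the 24 bp reads, IgG included, and is no difference between antibodies. Position 107673044 of chromosome 7 had 2450 reads in IgG at 8 h and at most 2 in any other library.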
